A study of Mus musculus with 4 samples.

How the data were processed

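Gastrocnemius RNA of male SOD1G93A mice with floxed Hdac4, without or with a myogenin-driven Cre, was compared at 14 weeks. Per the labels and the series design text, RNA of 6 and 5 animals was pooled and libraries were made in duplicate. Groups and replicate numbers were taken from the sample titles, and the columns of the count table were matched to samples by the initials and number that column name and title share. No label says that the duplicates came from separate pools, so p-values measure only the spread between these libraries.

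Per the labels' protocols, stranded mRNA libraries were sequenced single-end on a HiSeq 2500 to 56.4 M reads per sample on average (47.6 to 76.8 M), reads were trimmed with ERNE to a minimum length of 35 and with Cutadapt, and aligned with TopHat to GRCm38, with Cuffdiff for comparison. The submitters' processing notes name kallisto 0.43.1 and DESeq2 1.20.0. Which of these programs made which file is not given in the sources used here. The authors deposited a table of whole-number counts per gene symbol, not normalized, which may be rounded estimated counts if kallisto made them. The authors also deposited a table of their own comparison with the mean normalized count, the log2 fold change, its standard error, a test score and p-values, and per the file headers its columns carry DESeq2's names. Every adjusted p-value in that deposited table is below 0.01. Genes that share reads with paralogs, and transcripts of one gene, could have been split by either program, which changes counts per gene.

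The count table held 29953 named genes and 1 row with no name, which was left out (at most 0.0149% of a library). Gene symbols were matched to GENCODE vM21 (GRCm38), with 28086 matching 1 gene, and 3 list members were found through RefSeq synonyms (Mymk as Tmem8c, Mymx as Gm7325, Adgre1 as Emr1). Totals of 35320565 to 51328639 counts set the counting precision. A count of 0 was treated as a floor of 3 counts over the group, and exact intervals at 95% cover counting error only.

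The test planned before the data were examined was edgeR 4.0.16's quasi-likelihood F test (R 4.3.3; TMM scaling, filterByExpr with a minimum count of 10, robust fit, design with the group alone) on 13689 genes, with Benjamini-Hochberg adjustment at 0.05. CPM values are TMM-scaled. Errors of log2 fold changes are standard errors from edgeR. DESeq2 1.42.0 (Wald test, no independent filtering) and limma-voom (limma 3.58.1) were also run. DESeq2's adjusted p-values are named as such. The test of gene lists was limma camera on log2 CPM (prior count 2) with a preset correlation of 0.01 over 39 lists fixed beforehand with at least 3 measured members, and with an estimated correlation and fry beside it.

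The naming rule fixed beforehand took Hdac4, Sod1, Myog and Ucp1, the 10 largest changes in each direction among genes past edgeR's threshold with a mean log2 CPM of at least 1 and no overlap between groups, leaving out predicted-gene symbols, and up to 4 members of each list past the threshold, or the 2 most abundant where fewer than 2 passed. Because edgeR called 2 genes, the same rule was applied after the data had been seen to DESeq2's calls as well. Chrne, Chrnb1 and Myh4, and the lymphocyte and fat genes given as counts per library, were named after their values were seen. Some genes that these rules name are not reported here.

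The scripts were tested on simulated counts with 200 genes changed by known folds. With dispersion from the trend, edgeR called 25.5%, 61.2% and 74.0% of tested genes changed 2-, 4- and 8-fold and DESeq2 40.4%, 71.4% and 88.0%, with 2 and 18 unchanged genes called among 13443 tested. With dispersion varying between genes as fitted, edgeR and voom called 0% at every fold and DESeq2 17.8%, 68.1% and 87.5%, with 130 unchanged genes called by DESeq2 among 13243 tested. The alternatives tried were other scalings, filters, tools and thresholds, a replicate block, and leaving out each library. Some were added after the data were seen: leaving out libraries, a replicate block and an adjusted p under 0.01 in DESeq2, genes with 1 annotated transcript alone, and genes with equal means in both files. Other splits of the libraries were tested too. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.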

Results

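RNA was sequenced from gastrocnemius muscle of male mice that carry the SOD1G93A transgene, a model of amyotrophic lateral sclerosis in which motor neurons are lost and muscle is denervated. One group (SOD) had loxP-flanked Hdac4 alleles without Cre, and the other (SOD_HDAC4mKO) also carried a Cre recombinase driven by the myogenin promoter, which removes Hdac4 in skeletal muscle. HDAC4 is a class IIa histone deacetylase that accumulates in denervated muscle. The muscles were taken at 14 weeks of age from 6 SOD and 5 SOD_HDAC4mKO mice, the RNA was pooled, and each group is represented by 2 libraries. The count table held 51328639 and 35320565 counts for SOD replicates 1 and 2, and 37406783 and 39524541 for SOD_HDAC4mKO replicates 1 and 2. Mitochondrially encoded genes took 27.7% and 21.5% of the SOD counts and 24.7% and 25.8% of the SOD_HDAC4mKO counts.

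The comparison asks how muscle gene expression differs when Hdac4 is deleted in muscle of SOD1G93A mice. Hdac4 itself (ENSMUSG00000026313.16, GRCm38 chromosome 1, 91928779 to 92195699, minus strand) had 5667 and 7779 counts in the SOD libraries and 1535 and 1500 in the SOD_HDAC4mKO libraries. In CPM (counts scaled by TMM to a library total of 1e6) this was 153 ± 51.0 (SD, n = 2) against 41.5 ± 4.08 (SD, n = 2), a log2 fold change of -1.88 ± 0.27 (SE). DESeq2 called Hdac4 lower (adjusted p = 1.13e-08), and edgeR's quasi-likelihood test gave an adjusted p = 0.118. Without SOD replicate 1 Hdac4 passed in edgeR (adjusted p = 0.0315), and over the alternatives planned beforehand its adjusted p ran from 8.46e-09 in DESeq2 to 0.321 in edgeR without SOD_HDAC4mKO replicate 2. The count table gives 1 value per gene, so deleted and remaining exons, and muscle and other cells, are not separated. Sod1 (ENSMUSG00000022982.10) had 385 and 357 CPM in the SOD libraries and 358 and 312 CPM in the SOD_HDAC4mKO libraries, a log2 fold change of -0.15 ± 0.16 (SE).

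Muscle of SOD_HDAC4mKO mice had far less of the transcripts for a muscle fusion protein and for a growth factor. Gm7325, the symbol that the file uses for myomixer (Mymx), a micropeptide needed for myoblast fusion, fell from 28.7 ± 0.748 CPM to 0.381 ± 0.00725 CPM (SD, n = 2 each), 74.6-fold lower. Gdf5, a ligand of the bone morphogenetic protein family (ENSMUSG00000038259.4, GRCm38 chromosome 2, 155941023 to 155945367, minus strand), fell from 28.0 ± 1.46 CPM to 0.941 ± 0.0194 CPM, 29.7-fold lower. These 2 genes were the only ones of 13689 tested that edgeR's quasi-likelihood test called with all 4 libraries, both at an adjusted p = 0.0118, and both lost the edgeR call without SOD replicate 2 or either SOD_HDAC4mKO library. Gm7325 has a predicted-gene symbol and lay outside the naming rule on that ground; it is named because only 2 genes passed.

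By edgeR 0 genes were higher and 2 lower, with 1196 higher and 1356 lower at an unadjusted p under 0.05. limma-voom called 0 genes higher and 0 lower, and DESeq2 on the same genes called 439 higher and 600 lower. Without SOD replicate 1 edgeR called 104 genes higher and 194 lower, and without any one of the other 3 libraries it called 0 and 0. DESeq2 called 754 higher and 637 lower without SOD replicate 1, 244 and 236 without SOD replicate 2, 189 and 340 without SOD_HDAC4mKO replicate 1, and 111 and 296 without SOD_HDAC4mKO replicate 2. In simulated libraries of this size whose dispersion varied between genes as in the data, edgeR and voom called 0% of genes changed 8-fold. DESeq2 called 87.5% of them, but also 130 unchanged genes, 61.3% of all its calls there. With dispersion from the trend, edgeR called 74.0%, voom 72.0% and DESeq2 88.0% of genes changed 8-fold, and 15.1% of DESeq2's calls were unchanged genes. All these shares depend on the 200 genes set to change. They do not give the share of changed genes that edgeR can call in the real data. Nor do they give the share of unchanged genes among the real calls. With 2 libraries against 2 no exact permutation test can give a p below 0.333, and all p-values here measure only the spread between libraries of pooled RNA, which may be technical. Of the tested genes, 54.2% had no overlap between the groups. Chance gives 33.3% for a single gene, which would be a benchmark for this share only if genes varied independently between libraries. The genes below are described by DESeq2's calls, a choice made after the edgeR result had been seen. Except for Gm7325 and Gdf5 by edgeR, edgeR and voom called none of them. Most named genes were picked for large changes among DESeq2's calls, within a list or over all genes. How their calls held without 1 library, given next, therefore does not describe all 1039 calls. Of 93 named genes that DESeq2 called, 46 were also called in each of the 4 fits that left out 1 library.

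**Figure D1:**
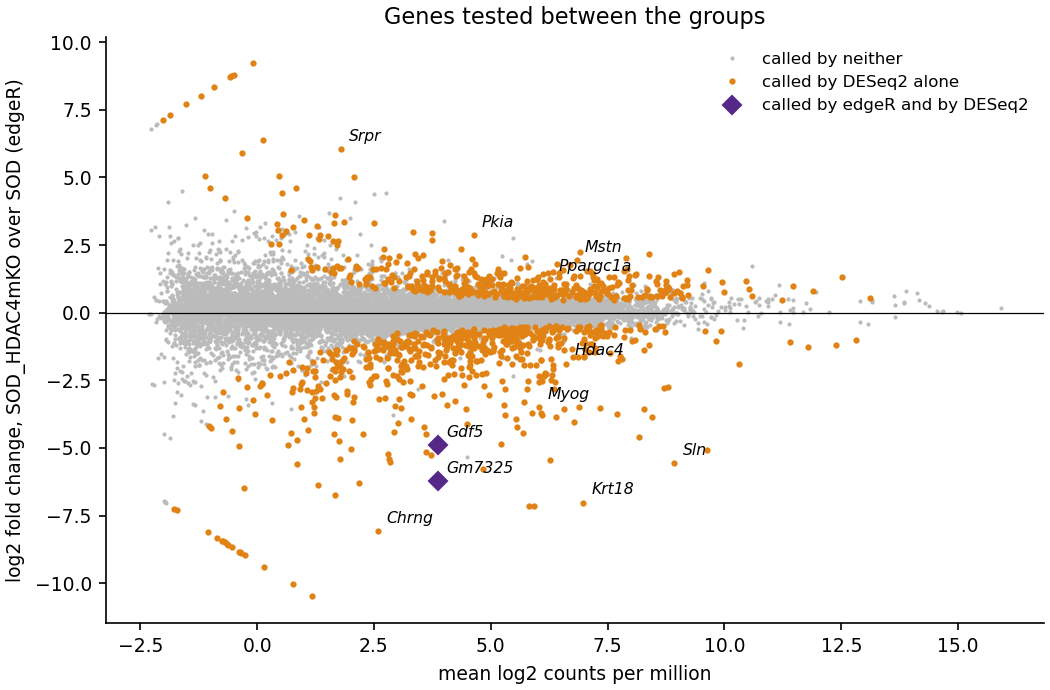
Log2 fold change of SOD_HDAC4mKO over SOD (vertical axis, edgeR) against mean log2 CPM (horizontal axis) for the 13689 genes tested. Orange points are genes called by DESeq2 alone, purple diamonds the 2 genes called by edgeR too, and the straight lines of points at the left edges are genes with 0 counts in one group, whose fitted fold change depends on the prior count.

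Transcripts of 4 acetylcholine receptor subunits were lower in SOD_HDAC4mKO muscle. Chrng, the fetal gamma subunit that denervated muscle re-expresses (GRCm38 chromosome 1, 87204657 to 87212694), had 332 and 693 counts in SOD against 1 and 2 in SOD_HDAC4mKO, a ratio of 279.9 with a 95% counting interval of 95.5 to 1359. Chrnd had 151 ± 91.3 CPM in SOD and 3.49 ± 0.171 CPM in SOD_HDAC4mKO (log2 fold change -5.43 ± 0.55, SE), and Chrna1 569 ± 277 CPM and 48.7 ± 11.0 CPM (-3.55 ± 0.43). Of 14 endplate and acetylcholine receptor genes, DESeq2 called 5 lower, these 3, Chrnb1 (-1.62 ± 0.30) and the receptor kinase Musk (-1.84 ± 0.45), and 0 higher. Musk lost its DESeq2 call without SOD replicate 2 or SOD_HDAC4mKO replicate 2. The adult subunit Chrne had a log2 fold change of -0.16, and Prkar1a, the most abundant member with Chrna1, one of -0.27 ± 0.16. edgeR called 0 members over all genes and 5 lower when adjusted over the list alone. camera with a preset correlation called the list lower (limma camera, adjusted p = 9.32e-04), a call lost at an adjusted p = 0.883 with an estimated correlation.

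Some genes that respond to loss of innervation were lower too: of 17, 11 had a fold below 1 and 6 a fold above 1. Myog, the muscle transcription factor myogenin (ENSMUSG00000026459.5, GRCm38 chromosome 1, 134289989 to 134292548), had 120 ± 39.2 CPM in SOD and 10.6 ± 1.95 CPM in SOD_HDAC4mKO (SD, n = 2 each; log2 fold change -3.50 ± 0.31, SE). Sln, which encodes the calcium pump regulator sarcolipin, had 954 ± 502 CPM and 20.2 ± 7.40 CPM (-5.56 ± 0.56), and Gadd45a, a growth arrest gene, 556 ± 187 CPM and 23.3 ± 1.33 CPM (-4.58 ± 0.31). Of these denervation-responsive genes DESeq2 called 9 lower, among them Ankrd1 (-3.84 ± 0.52), and 1 higher, Ky (1.33 ± 0.29), a gene needed for normal muscle. The same genes were called when any 1 library was left out. edgeR called 0 members over all genes, and 2 higher and 9 lower when adjusted over the list alone. camera called the list lower (limma camera, adjusted p = 0.00197), with an adjusted p = 0.883 with an estimated correlation. The denervation genes differed between the SOD libraries too: their median log2 ratio of SOD replicate 2 over SOD replicate 1 was 0.70.

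**Figure D2:**
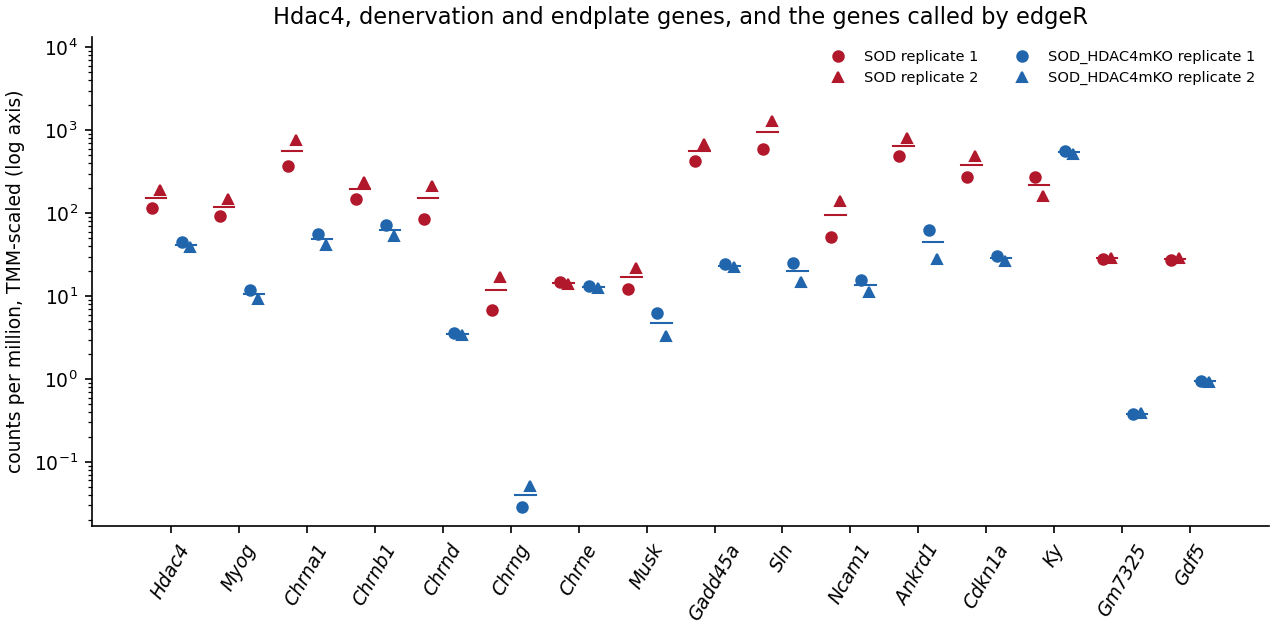
TMM-scaled CPM (log axis) of 16 genes in each of the 4 libraries. Circles are replicate 1 and triangles replicate 2, red is SOD and blue SOD_HDAC4mKO, and short lines are the means of 2 libraries; Myog lies at 120 CPM in SOD and 10.6 CPM in SOD_HDAC4mKO, while Chrne differs little.

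Several embryonic and fusion genes were lower as well. Tmem8c, the file's symbol for myomaker (Mymk), which acts with myomixer in fusion, had a log2 fold change of -4.11 ± 0.65 (SE), Myh3, the embryonic myosin heavy chain, one of -3.55 ± 0.75, the cell adhesion gene Ncam1 one of -2.81 ± 0.53, and the myogenic factor Myf6 one of -1.59 ± 0.25. Of 13 developmental and regeneration muscle genes, whose median log2 ratio of SOD replicate 2 over SOD replicate 1 was 0.63, DESeq2 called 8 lower and 0 higher. Of these 8, 7 kept the call in every fit that left out 1 library, and Myh3 lost it without SOD replicate 2 (adjusted p = 0.327). Actc1, the cardiac actin, overlapped between the groups, with a fold of -0.95 ± 0.46 (log2). edgeR called 1 lower over all genes, Gm7325, and 9 lower when adjusted over the list alone. camera called the list lower (limma camera, adjusted p = 1.70e-05), with an adjusted p = 0.883 with an estimated correlation. Of 6 satellite cell markers DESeq2 called 1 lower, the syndecan Sdc4 (-0.92 ± 0.12), a call lost without either SOD_HDAC4mKO library, and Notch3 had -0.18 ± 0.13. Sdc4 was also the 1 member that edgeR called when adjusted over the list alone, and camera did not call the list.

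With predicted-gene symbols such as Gm7325 and genes with a mean log2 CPM under 1 left out, the 10 genes furthest below SOD in DESeq2's calls were Chrng and Sln, named above, and 8 genes outside the lists. Nrcam, a neuronal cell adhesion gene, had 0 counts in both SOD_HDAC4mKO libraries and 383 in SOD, at least 104.6-fold lower against a floor of 3 counts over the group. Aldh3a1, an aldehyde dehydrogenase, had a log2 fold change of -7.14 ± 0.67 (SE), the keratins Krt8 and Krt18, which pair in simple epithelia, -7.14 ± 0.72 and -7.02 ± 0.59, and Tmem151a, Clca3, Bpifb1 and Aif1l lay between -6.74 and -5.76. Among the 10 genes furthest above SOD by the same rule, Pkia, the inhibitor of protein kinase A, had 2.86 ± 0.25, Arhgap5 2.99 ± 0.28, Srpr, a signal recognition particle receptor, 6.03 ± 0.79, and Cntnap2 2.95 ± 0.68. Plekhd1, Col9a1 and Rps12l1 had log2 fold changes from 2.84 to 3.30, and each lost the DESeq2 call without SOD replicate 2 or SOD_HDAC4mKO replicate 1. Spib and Acap1, lymphocyte genes, had 261 and 310 counts in SOD_HDAC4mKO replicate 2 and at most 23 in any other library, and their DESeq2 call ended without that library (adjusted p = 1 for both) or without either SOD library.

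Genes of glycolysis and glycogen use had a higher median in SOD_HDAC4mKO muscle. Eno3, muscle enolase, had 1.14 ± 0.45 (log2 fold change, SE) and Phka1, a phosphorylase kinase subunit, 1.24 ± 0.44; they were among the 3 of 17 that DESeq2 called higher, with 0 lower. Without SOD replicate 1 DESeq2 called 13 higher, without SOD_HDAC4mKO replicate 1 it called 0, and without either other library 1, and none of the 3 calls held in all these fits. edgeR called 0 over all genes and 0 adjusted over the list alone. camera called the list higher (limma camera, adjusted p = 0.00996), with an adjusted p = 0.883 with an estimated correlation. Camera's adjusted p was 0.161 without SOD replicate 2 and 0.0551 without SOD_HDAC4mKO replicate 2. SOD replicate 2 lay lower than SOD replicate 1 in this list, with a median log2 ratio of -0.89. Of 44 oxidative phosphorylation genes DESeq2 called 0, edgeR 0 and edgeR adjusted over the list alone 0; the median log2 fold change was 0.02, with Sdha at 0.16 ± 0.26. That list was called higher by camera without SOD replicate 1 (adjusted p = 6.25e-05) and lower without SOD replicate 2 (adjusted p = 2.41e-05), so its direction rests on which SOD library is used. Of 20 fatty acid oxidation genes DESeq2 and edgeR called 0 (median log2 fold change 0.12; Pdk4 0.50 ± 0.21), and of 13 mitochondrially encoded genes both called 0 (median 0.17), though DESeq2 called 10 higher without SOD replicate 1. Adjusted over the list alone edgeR called 0 in both lists. Ppargc1a, a coactivator of mitochondrial genes, was the 1 of 8 brown fat and thermogenic genes that DESeq2 called higher (1.24 ± 0.23), though not without SOD_HDAC4mKO replicate 1, and edgeR adjusted over the list alone called it higher and 1 member lower.

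**Figure D3:**
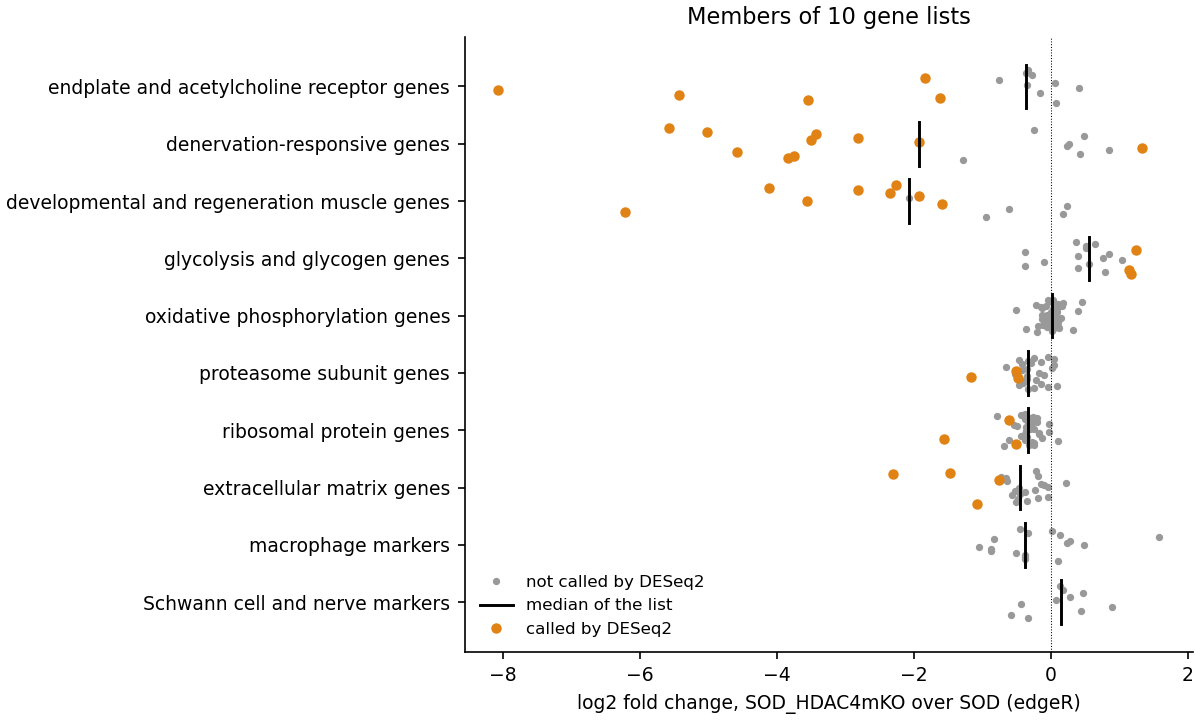
Log2 fold change of SOD_HDAC4mKO over SOD (horizontal axis, edgeR) for each tested member of 10 gene lists. Orange points were called by DESeq2, grey points were not, and the black bar is the median of the list, -1.93 for denervation-responsive genes and 0.02 for oxidative phosphorylation genes.

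Contractile and calcium genes lay on both sides of SOD. Of 14 fast fibre contractile genes DESeq2 called 3 higher and 2 lower: Mybpc2, fast myosin-binding protein C, had 1.33 ± 0.42 (log2 fold change, SE) and Myh2, the type IIa myosin heavy chain, -1.27 ± 0.23. Atp2a1, the fast-fibre calcium pump, had -2.52 ± 0.52. Of 13 slow fibre genes it called 0 higher and 2 lower, myoglobin Mb (-1.20 ± 0.26) and Csrp3 (-1.80 ± 0.26), while Myh7 had 0.40 ± 0.31. Of 18 calcium handling genes it called 3 higher, including the ryanodine receptor Ryr1 (0.79 ± 0.26) and Camk2a (1.34 ± 0.43), and 1 lower, Sln. Ryr1 and Camk2a lost the DESeq2 call without either SOD_HDAC4mKO library. Of 14 dystrophin complex genes it called 1 higher, Sgcd (1.10 ± 0.15), with 0 lower. Without SOD replicate 1 DESeq2 called 8 fast fibre genes higher, without SOD_HDAC4mKO replicate 1 it called 0 higher in any of these lists, and without SOD_HDAC4mKO replicate 2 it called 1 fast fibre gene higher and 0 in the others. The calls that held in every fit without 1 library were Myh2, Atp2a1, Mb, Csrp3 and Sln. edgeR called 0 members of these 4 lists over all genes; adjusted over the list alone it called 2 fast fibre, 2 slow fibre and 1 calcium handling gene lower and 1 dystrophin complex gene higher. camera called none of the 4. Leaving out libraries cannot show an error in how a gene's reads were assigned in every library. Atp2a1 is absent from the authors' deposited table. Myh4, a fast fibre gene not called here, has a log2 fold change of 1.29 there.

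Proteasome and ribosomal protein genes lay below SOD by a small margin. They differed between the SOD libraries too, with median log2 ratios of replicate 2 over replicate 1 of 0.07 and 0.21. Of 31 proteasome subunit genes DESeq2 called 3 lower, led by Psmb5 (-1.16 ± 0.13, log2 fold change, SE), with 0 higher, and the median of the list was -0.33. Of 39 ribosomal protein genes it called 3 lower, among them Rpl3 (-1.56 ± 0.30), with 0 higher and a median of -0.33. Without SOD replicate 1 these counts were 9 and 11 lower, and without any one of the other libraries at most 1 in each list. edgeR called 0 in both lists over all genes, and 1 proteasome gene lower and 0 ribosomal genes adjusted over the list alone. camera called both lists lower (limma camera, adjusted p = 5.64e-05 and 1.90e-06), each with an adjusted p = 0.883 with an estimated correlation. Of 14 atrophy ubiquitin ligase genes DESeq2 called 1 higher, Fbxo40, and 2 lower, Fbxo30 (-1.15 ± 0.14) and Mdm2 (-1.26 ± 0.22). The main atrophy ligases Trim63 and Fbxo32 had log2 fold changes of -0.03 ± 0.20 and 0.12 ± 0.17, and that of Fbxo32 was -0.02 with scaling by library totals. Of 21 autophagy and lysosome genes DESeq2 called 0 higher and 4 lower, including Map1lc3a (-1.39 ± 0.26) and Ctsl (-0.94 ± 0.15), and 1 to 4 lower without 1 library. edgeR adjusted over the list alone called 2 lower in each of these lists and camera called neither. In the 4 lists of this paragraph Psmb5, Fbxo30 and Map1lc3a alone kept the DESeq2 call in every fit that left out 1 library.

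Matrix genes lay below SOD, with 4 of 24 called lower by DESeq2 and 0 higher. Their median log2 fold change was -0.46, and their median log2 ratio of SOD replicate 2 over SOD replicate 1 was 0.28. Tgfb1, a matrix-inducing cytokine, had -2.30 ± 0.33 (log2 fold change, SE), and Timp1, a metalloproteinase inhibitor, -1.46 ± 0.29. Col1a2, the most abundant member with Sparc, had -0.35 ± 0.20. Without SOD replicate 1 DESeq2 called 8 lower, and without any one of the other libraries 1 lower; Tgfb1 kept the call throughout and Timp1 did not. edgeR called 0 over all genes and 4 lower adjusted over the list alone. camera called the list lower (limma camera, adjusted p = 1.28e-04), with an adjusted p = 0.883 with an estimated correlation. Of 13 fibro-adipogenic and tendon markers DESeq2 called 1 lower, the tendon factor Scx (-1.89 ± 0.25), which edgeR also called when adjusted over the list alone, and camera did not call the list.

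Growth, stress and signalling genes were mixed. Of 17 growth and myostatin signalling genes DESeq2 called 2 higher, myostatin Mstn (1.94 ± 0.40, log2 fold change, SE) and the insulin receptor substrate Irs1 (1.31 ± 0.16), and 4 lower, among them follistatin Fst (-2.53 ± 0.43) and Id2 (-2.45 ± 0.24). Of 14 p53 and apoptosis genes it called 1 higher and 5 lower, including the cell cycle inhibitor Cdkn1a (-3.75 ± 0.35). Of 13 heat shock genes it called 1 higher, Cryab (1.30 ± 0.25), and 2 lower, Hspb8 (-1.91 ± 0.31) and Hspb7 (-1.05 ± 0.23). Of 17 integrated stress response genes it called 1 lower, Mthfd2 (-2.30 ± 0.35), of 20 oxidative stress defence genes 2 lower, Gpx3 (-1.18 ± 0.15) and Prdx6 (-0.64 ± 0.14), and of 17 immediate-early genes 1 higher, Nr4a3, and 2 lower, Jun (-1.32 ± 0.22) and Junb (-1.41 ± 0.16). Of 14 circadian clock genes it called 2 higher, among them Hlf (1.44 ± 0.30). Among 9 class II HDAC and MEF2 genes Hdac4 alone was called, and of 12 polyamine genes and 13 cell cycle genes none was. The calls of these 10 lists that held in every fit without 1 library were Mstn, Irs1, Fst, Id2, Cdkn1a, Hspb8, Mthfd2, Gpx3, Jun, Junb and Hdac4; the others were lost in at least 1 fit. edgeR called 0 members of these 10 lists over all genes. Adjusted over the list alone it called 2 higher and 4 lower for growth, 6 lower for p53, 1 higher and 2 lower for heat shock, 1 lower each for the stress response, oxidative stress and HDAC lists, 2 lower for immediate-early genes, and 0 for the others. Without SOD replicate 2 or SOD_HDAC4mKO replicate 1 DESeq2 called 0 circadian and 0 immediate-early genes higher. It called 4 immediate-early and 4 polyamine genes higher without SOD replicate 1, and without SOD replicate 2 it called 2 polyamine genes higher. limma's fry called the integrated stress response list lower (adjusted p = 0.0305), and camera called none of the 10.

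Among markers of other cell types, leukocyte and adipocyte markers differed between the SOD_HDAC4mKO libraries, while macrophage and endothelial markers differed more between the SOD libraries (median log2 ratio of replicate 2 over replicate 1 of 0.60 and -0.44) than between the SOD_HDAC4mKO libraries (0.47 and 0.22). Of 11 adipocyte markers DESeq2 called 2 higher, Adipoq (1.24 ± 0.43, DESeq2's log2 fold change and SE) and Scd1 (1.41 ± 0.47), and 1 lower, Car3 (-1.01 ± 0.32). Adipoq lost its DESeq2 call without SOD replicate 1 or SOD_HDAC4mKO replicate 2, and Scd1 without any library but SOD_HDAC4mKO replicate 1. Ucp1, the uncoupling protein of brown fat, had 0, 0 and 0 counts in the other libraries and 305 in SOD_HDAC4mKO replicate 2. The 10 other leukocyte markers had a median log2 ratio of SOD_HDAC4mKO replicate 2 over replicate 1 of 2.64, with Ptprc at 5.67 and 48.5 CPM, and DESeq2 and edgeR called 0 of them; without SOD_HDAC4mKO replicate 1 DESeq2 called 8 higher. Neither tool called any of the 17 macrophage, 12 endothelial, 10 Schwann cell and nerve, 5 erythroid or 4 sex-linked markers. Of 9 smooth muscle and pericyte markers DESeq2 called 1 higher, Abcc9, of 15 interferon-stimulated genes 1 lower, Irgm1 (-1.17 ± 0.31), and of 12 inflammatory genes 1 lower, Tnfrsf12a (-0.98 ± 0.11). None of the DESeq2 calls in this paragraph held in every fit that left out 1 library. Adjusted over the list alone, edgeR called Tnfrsf12a and 0 members of the other lists in this paragraph, and camera called none of these lists. Over the 39 lists, camera with a preset correlation called 1 higher and 6 lower, with an estimated correlation 0, and fry 1. In simulated data camera with an estimated correlation also missed a list that had been changed. Genes were drawn independently there, so it cannot show whether the calls with a preset correlation hold where list genes vary together. Median, mean and test direction disagreed in sign for the calcium handling, heat shock, immediate-early, brown fat, erythroid, slow fibre and inflammatory lists.

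The authors' deposited table lists 849 genes with an adjusted p below 0.01, 324 higher and 525 lower in SOD_HDAC4mKO. DESeq2 on the count table called 623 of them (73.4%) in the same direction, and edgeR 2 (0.236%). These calls were made at an adjusted p under 0.05, a looser threshold. Both shares are of all 849 genes, tested here or not. Of the 766 tested here, 750 had the same sign of log2 fold change and 16 the opposite. Some genes named above that DESeq2 called here are absent from the authors' deposited table, among them Pkia, Cntnap2, Bpifb1, Clca3, Atp2a1, Musk and Mdm2. Mean counts differ between the 2 files for many genes. Of 811 genes of the authors' deposited table with a row in the count table, 398 (49.1%) had a mean normalized count within 10% of the authors' mean, 219 lay below 50% of it, and 13 were at 0. Myh4, the type IIb myosin heavy chain, has a mean of 1904300 and a log2 fold change of 1.29 in the authors' deposited table, but a mean of 7544 in the count table and a log2 fold change of -0.07 ± 0.28 (SE) here. Hdac4 has a log2 fold change of -1.39 in the authors' deposited table, whose mean is 0.345 times that of the count table, and Srpr one of 0.63, with 90.0 times the mean. Genes whose means differ by more than 2-fold, also Arhgap5, Chrng, Nrcam, Aif1l, Rpl3, Bgn and Psmb5, are uncertain in size for that reason, and paralogous genes such as the myosins, keratins and ribosomal proteins because shared reads could be split. The sizes for Aldh3a1, Tmem151a, Krt8 and Myh3 are uncertain too, since the authors' deposited table gives log2 fold changes of -3.07, -3.76, -2.89 and -1.66. For Nrcam, Chrng, Aif1l and Arhgap5 it gives -4.51, -5.69, -4.43 and 0.63. Its falls for Nrcam and Chrng are smaller than the lower bounds given above, which cover counting error in the count table only. Annotated exons of other genes overlap Hdac4, Gdf5, Krt8, Gadd45a, Cdkn1a, Ncam1, Fst, Jun, Junb, Irs1, Mb, Myh2, Atp2a1, Ryr1, Aif1l, Srpr, Cryab, Abcc9 and Mybpc2 on the opposite strand and Ctsl, Psmb5 and Rpl3 on the same strand, and whether counting used strand is not given in the sources used here.

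**Figure D4:**
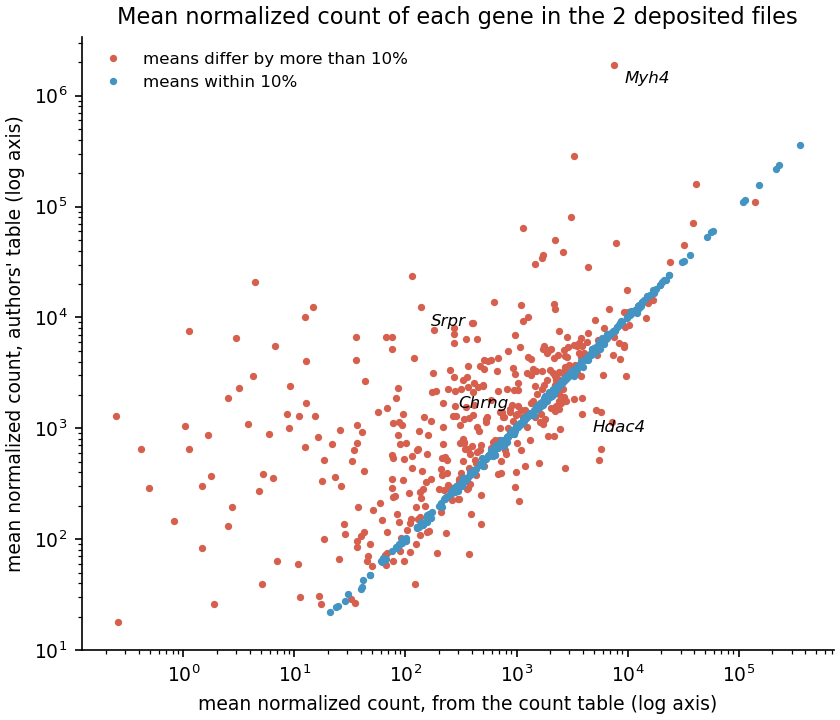
Mean normalized count in the authors' deposited table (vertical log axis) against the mean computed from the count table (horizontal log axis) for 798 genes with a mean above 0. Blue points (398 genes) have means within 10% of each other and red points do not; Myh4 stands at 1904300 against 7544.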

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

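The DESeq2 fits that left out a library, had a replicate block or used an adjusted p under 0.01, the fits on genes with 1 annotated transcript and the overlap over genes with equal means were chosen after the result was seen. edgeR called 0 genes higher and 2 lower with every other scaling and filter tried, with legacy quasi-likelihood and with a 1.5-fold test. DESeq2 called 439 higher and 600 lower on the same genes. On all genes, with its independent filtering set for 0.01 and calls still made at 0.05, DESeq2 called 432 and 599. limma-voom called 0 lower, as did edgeR at an adjusted p under 0.01. With genes of 1 annotated transcript alone, edgeR called 1 lower. The replicate numbers are not said to pair libraries, and deviations of same-numbered libraries correlated at 0.0234. With the replicate block edgeR called 4 lower, and DESeq2 322 higher and 391 lower. DESeq2 called 237 higher and 414 lower at an adjusted p under 0.01, and 50 higher and 81 lower on genes with 1 annotated transcript. Leaving out 1 library in turn, where the lone library is assumed to vary like the other group, gave 0 to 104 higher and 0 to 194 lower by edgeR, and 111 to 754 higher and 236 to 637 lower by DESeq2. The cause was not tested.

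The overlap with the authors' deposited table, 0.236% by edgeR, was 73.4% and 73.3% with the DESeq2 fits, 0% with limma-voom, 0% at an adjusted p under 0.01, and 0% to 24.3% without 1 library. Hdac4 kept its direction under every alternative, passing in DESeq2 (-1.89 on the same genes and -1.90 on all genes, log2) and without SOD replicate 1 (range without 1 library -2.24 to -1.52). Lists called higher, 1 by camera, numbered 0 with an estimated correlation, 0 by fry, 2 with voom-weighted values, 2 with DESeq2 size factors, 2 with 50 or more counts in at least 2 libraries, 2 with the replicate block and 1 to 3 without 1 library. Lists called lower, 6 by camera, numbered 0 with an estimated correlation, 1 by fry and 7 to 9 without 1 library.

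Of 153 named genes tested, 133 kept their direction under every alternative and 20 did not; none of these 20 was called by edgeR or DESeq2 with all libraries. Scaling by library totals, which moved the median log2 fold change of all genes from 0.02 to -0.11, gave Atp5b -0.11, Dmd -0.0048, Fbxo32 -0.019, Lyz2 -0.017, Mcpt4 -0.088, Psmd1 -0.14 and Tef -0.047. With no filter Atp5b was at -0.0027 and Psmd1 at -0.0042. With 50 or more counts mt-Co3 was at 0.0048 and Oaz1 at 0.0059, with limma-voom Mcpt4 was at -0.072, mt-Co3 at 0.060 and Oaz1 at 0.0091, with the replicate block -0.078, 0.053 and 0.0056, and on genes with 1 annotated transcript mt-Co3 was at 0.0020. Without 1 library the ranges were Atp5b -0.22 to 0.21, Cdh5 -0.24 to 0.15, Cox8b -0.25 to 0.50, Dmd -0.084 to 0.37, Eif2s3y -0.074 to 0.0085, Kdr -0.42 to 0.11, Lyz2 -0.16 to 0.36, Mcpt4 -0.72 to 0.50, mt-Co1 -0.13 to 0.46, mt-Co3 -0.38 to 0.41, Oaz1 -0.16 to 0.10, Psmd1 -0.12 to 0.12, Ptprc -0.30 to 2.76, Rgs5 -0.24 to 0.48, Rps2 -0.11 to 0.044, Sdha -0.12 to 0.42, Smad3 -0.019 to 0.39, Tef -0.16 to 0.32 and Trim63 -0.24 to 0.12. By limma camera the oxidative phosphorylation genes turned lower without SOD replicate 2 (adjusted p = 2.41e-05; range 2.41e-05 to 0.956), and the other leukocyte markers turned lower without SOD_HDAC4mKO replicate 2 (adjusted p = 0.00605; range 1.07e-05 to 0.636). The cause was not tested.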

Other observations

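Tests on the difference between the SOD libraries and on the difference between the 2 deposited files were chosen after the result was seen, as was the set of 4 genes with 1 annotated transcript; the other tests were written before.

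Lymphocyte genes and some fat genes stood high in SOD_HDAC4mKO replicate 2 alone: the B cell receptor gene Cd79a had 28, 29, 7 and 550 counts in SOD replicates 1 and 2 and SOD_HDAC4mKO replicates 1 and 2, the T cell receptor gene Trbc2 had 5, 2, 2 and 217, and Fasn, the fatty acid synthase, had 389, 421, 172 and 1662. Over 16 further B and T cell genes, listed before their values were seen, the median log2 ratio of SOD_HDAC4mKO replicate 2 over replicate 1 was 3.91, above 100% of random lists matched on mean expression, and over 14 further white fat genes it was 0.80, but 5 of these 14 and 3 of 11 adipocyte markers exceeded 2-fold, and Aqp7 (352, 78, 89 and 192 counts) and Cd36 (20045, 10633, 12480 and 12726) were highest in SOD replicate 1. Against a change brought by loss of HDAC4 in both libraries, the same B and T cell genes had a median log2 ratio of -0.56 in SOD_HDAC4mKO replicate 1 over the SOD mean. Against an effect of how reads are assigned among transcripts, 4 B and T cell genes with 1 annotated transcript had a median of 4.55; the filtered set held 1 such gene, so the set was widened after that was seen. Lymph node tissue carried into that pool may account for the lymphocyte genes. However, Cd74 (939, 1158, 575 and 985 counts), expected in B cells, was not high there. The 9 further brown fat genes had a median of 0.01, with 1 above 2-fold, as were 2 of the 8 in the fixed list. That median cannot decide on brown fat, since genes such as Fabp3 (474.7 to 776.6 CPM) were abundant in every library. Cd74 and Ucp1 stay open, as does fat tissue carried into the pool. The white fat median fits such fat, though most of the 14 genes did not exceed 2-fold. Cd36 (258.4 to 413.8 CPM) was abundant in every library, so it cannot test for added fat. Aqp7 was higher in SOD_HDAC4mKO replicate 2 than in replicate 1.

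The genes lower in SOD_HDAC4mKO muscle were also unequal between the SOD libraries. All 14 endplate and denervation list members that DESeq2 called lower were higher in SOD replicate 2 than in SOD replicate 1 (100%), by a median of 0.98 on the log2 scale, as were 91.2% of its 600 lower calls against 50.8% of tested genes. Of its 439 higher calls 79.3% were lower in SOD replicate 2, so SOD replicate 1 lay nearer SOD_HDAC4mKO for most calls in both directions, and not for denervation genes alone. Scaling between the libraries is argued against by the percentile of the denervation list among random lists matched on mean expression, 100. The SOD libraries differed by a chi-square of 150.5 per degree of freedom, which excludes counting noise, but a single pool prepared as 2 libraries also differs by preparation, which was not measured, so the bound of 2 set for that test was too strict and a single pool cannot be told apart from separate pools. A candidate explanation, which was not tested, is that the pools held muscle at different stages of denervation, and no label gives the animals of each library.

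The mean counts of the 2 deposited files differ for reasons left open. A count table that held 1 transcript per gene may account for means below the deposited ones: 4.82% of genes with 1 annotated transcript, 17.9% with 2 to 3 and 34.8% with 4 or more had a deposited mean over 2 times the count-table mean. It does not account for the 7.64% of genes with a count-table mean more than 25% above the deposited one, a share that was 13.3% among genes with 1 transcript, so at least part of the difference has another source. A different scaling of the same counts is argued against too, with 48.8% of genes within 10% of the median ratio. No biological explanation was tested for this difference.

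The 4 libraries can be split into 2 and 2 in 3 ways, too few for a share under 0.05. The real split gave 1039 DESeq2 calls and the highest other 17, and 2 and 0 by edgeR. In each case 1 of the 3 splits, the real one, gave as many. Each other split put 1 SOD and 1 SOD_HDAC4mKO library on each side. Any difference between the groups then counts as spread within a side and lowers the calls. Few calls in the other splits were therefore likely beforehand.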
